A study of Mus musculus with 6 samples.

How the data were processed

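Total RNA of 3 renal MSC samples and 3 JG cell samples from mice was extracted with a Picopure kit, and biotin-labelled cRNA made from 100 ng was hybridised to Affymetrix mouse arrays, per the labels. The MSC were sorted by CD44 and grown to confluence, per the labels, which repeat the MSC growth medium on the JG samples too, so whether JG cells were cultured is open. The deposited table holds a linear intensity per probe set and array. How the authors summarised probes, subtracted background and scaled the arrays is not given in the sources used here. Array medians were 34.06, 27.3 and 29.58 for MSC samples 1 to 3 and 27.41, 28.96 and 36.5 for JG samples 1 to 3, and the means after trimming 2% at each end were 197, 194, 212, 198, 153 and 194 in that order. The arrays were therefore not quantile normalized or scaled to 1 common trimmed mean. Between 868 and 1311 values per array were exactly 1, and 34.4% to 41.5% lay below 16. The table used here holds no detection calls, so a low value is reported as an intensity and not as absence. No genome build or coordinates were used.

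Of 45037 probe sets, 34945 were paired with 1 gene by the platform annotation, 932 with several genes and 9160 with no gene in that annotation, which leaves the last unnamed here. Gene identifiers of 34741 of the 34945 were found in a table of RefSeq genes for GRCm38.p6, and 0 symbols changed. Each of 18193 genes was represented by its brightest probe set over all 6 arrays. Another probe set was present for 9010 genes, and of 2790 called genes 1632 had one. For 649 of these another probe set was called in the same direction and for 17 one was called in the opposite direction.

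Values entered the tests as log2 of the intensity plus 16, with no further normalization and no filter. The pseudocount damps noise near the floor and understates changes of dim genes. The difference JG minus MSC was fitted with lmFit and eBayes in limma 3.58.1 (R 4.3.3) on all 6 samples without covariates, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A further count asked for at least a 2-fold difference. Gene lists (55, with 972 symbols, of which 78 were not measured) were tested with camera at a preset correlation of 0.01 between genes and adjusted over the lists, again with the correlation estimated from the data, and with fry. In each list the calls were also counted after adjustment over its members alone. Figures were drawn with matplotlib 3.10.9.

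The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule names the 10 genes with the largest difference in each direction among called genes whose groups do not overlap and whose higher mean exceeds the median of all genes, passing over gene models without a name. It also names Cd44 and Sox6, up to 4 called members of each list with the largest difference, and for lists of other cell types up to 4 members with the highest JG mean. Other called members of lists with few calls, and Col1a1, were named after their values were seen.

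The fit was tested on simulated data of the 18193 genes with the fitted variances, in 10 draws per size with 200 genes changed. A log2 change of 1 was recovered in 0% of changed genes, 2 in 42.2% and 4 in 95.2%, and 4.41% and 4.56% of the calls at the last 2 sizes were false. A planted list had an unadjusted camera p under 0.05 in 10 of 10 draws at each size and an unchanged list in 0 of 10. The genes were drawn independently, whereas the estimated correlation within a real list reached 0.573. These draws therefore do not show how often camera calls unchanged lists of correlated genes. Both groups were drawn with the same variance, whereas the median SD of a gene was 0.26 in MSC and 0.54 in JG. With only 200 changed genes the adjustment over all genes is also stricter than with the 2790 genes called here. For both reasons the recovery may differ in the real samples. Alternatives changed 1 part of the processing at a time: quantile normalization, median centring, filters on dim genes at the 25th percentile and the median, the mean of a gene's probe sets, a variance prior with an intensity trend and robust estimation together, array weights, the replicate number as a block, each sample left out, pseudocounts of 1 and 64 and an unmoderated t statistic. Leaving out probe sets with the suffix s or x, which can match several transcripts, was added after seeing the data.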

Results

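Juxtaglomerular (JG) cells are the renin-secreting cells of the kidney's afferent arteriole. In this series they were sorted by their yellow fluorescent protein from adult C57BL6 mice of a Ren1c reporter strain and compared with renal mesenchymal stromal cells (MSC), which were sorted from the same strain by the surface antigen CD44 and grown to confluence in serum. Total RNA was measured on 6 single-channel Affymetrix mouse arrays, 3 per group. Each array gave 45037 probe set intensities, and their medians ran from 27.3 in MSC sample 2 to 36.5 in JG sample 3. The arrays correlated at a mean of 0.973 within the MSC group, 0.860 within the JG group and 0.759 between the groups, across 18193 genes, and no pair of arrays held identical values. JG sample 1 stood nearest to MSC: it correlated at 0.887 with JG sample 3, 0.807 with JG sample 2 and 0.806 to 0.814 with the MSC samples. The median standard deviation of a gene on the log2 scale was 0.26 among the MSC samples and 0.54 among the JG samples. The labels do not say whether the samples of a group came from separate animals or cultures, so the p-values below measure the spread between these samples. Values in the text are mean intensity ± SD with n = 3 per group, log2 differences are JG minus MSC ± SE on the scale of log2 of the intensity plus 16, and adjusted p-values of genes are from limma. Where the dimmer group lies below 16, the log2 difference is set by the brighter group and the added 16, and is a lower bound on the size.

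The JG samples were marked by transcripts of kidney epithelium, and the largest differences in the MSC direction included matrix genes such as Tnc, Lox and Col11a1. The 10 genes with the largest differences upward in JG were Kap, Spink1, Slc34a1, Ugt3a2, Acss1, Umod, Slc27a2, Slc13a3, Akr1c21 and Cltrn, with log2 differences from 8.30 for Kap to 7.70 for Cltrn. All 10 lay below 16 in every MSC sample, so these are lower bounds and their order carries no meaning. Slc34a1, the sodium-phosphate cotransporter of the proximal tubule, had an intensity of 5156 ± 904 in JG and 1.18 ± 0.154 in MSC (8.22 ± 0.24, adjusted p = 4.52e-05). Umod, the uromodulin gene of the thick ascending limb, stood at 4823 ± 388 against 4.41 ± 2.36 (7.89 ± 0.22, adjusted p = 4.52e-05). The 10 with the largest differences in the MSC direction were Dkk3, Tnc, Cdh11, Trib3, Cldn11, Ccn4, Lox, Igfbp2, Col11a1 and Inhba, from -6.74 for Dkk3 to -5.80 for Inhba. Tnc, which encodes the matrix glycoprotein tenascin C, had 2687 ± 607 in MSC and 9.18 ± 2.49 in JG (-6.73 ± 0.26, adjusted p = 6.35e-05), again a lower bound on the size.

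Across all 18193 genes, limma called 2790 at an adjusted p under 0.05, of which 1401 were higher in JG and 1389 higher in MSC. At least 2-fold differences were called for 2742 genes (1374 and 1368). The groups did not overlap for 7041 genes, 38.7% of those tested, where chance gives 10%. The count of called genes was 1240, 1152 and 1139 without MSC samples 1, 2 and 3 in turn, and 5194 without JG sample 1. The 20 genes with the largest differences kept an adjusted p under 0.05 whichever sample was left out. Among all other named genes that were called, the highest adjusted p after leaving out 1 sample was 0.180, for Cd8a.

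**Figure D1:**
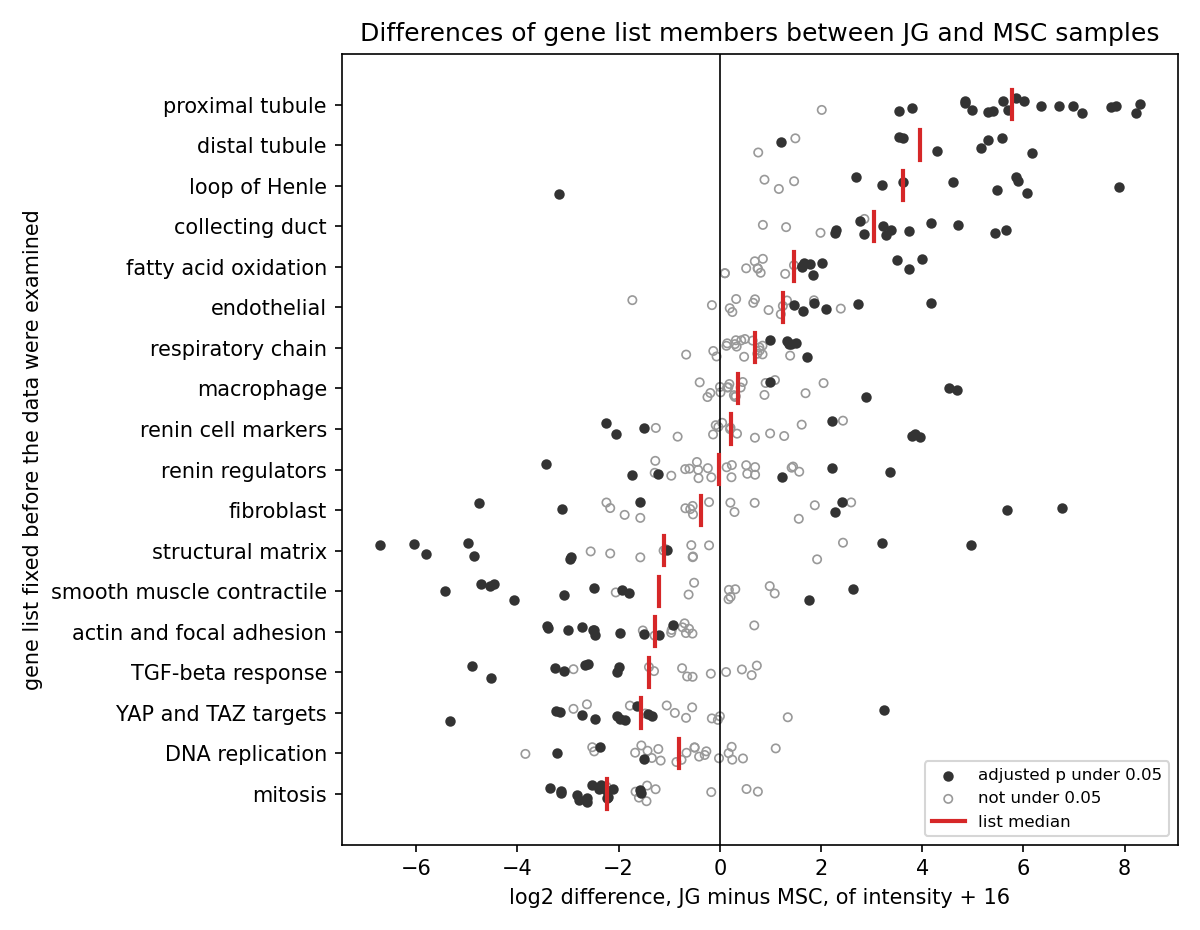
Log2 difference (JG minus MSC, of intensity plus 16) of each measured member of 18 gene lists. Filled points have an adjusted p under 0.05 (limma, 3 samples per group), open points do not, and the red bar is the list median, which is 5.77 for the proximal tubule list at the top and -2.23 for the mitosis list at the bottom.

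The genes used to choose the cells were looked at first, as a check of the labels. Cd44, the antigen of the MSC sort, was 974 ± 81.9 in MSC and 139 ± 17.3 in JG (-2.68 ± 0.22, adjusted p = 0.000832), and 3 of its 4 probe sets were called lower in JG. The fourth lay between 1.7 and 15.01 on all arrays. Ren1 was not analysed here, since none of the probe sets paired with 1 gene was paired with it. Probe sets paired with several genes were not used. Sox6, a transcription factor, was read by 4 probe sets that did not give 1 answer. Its brightest probe set was 132 ± 95.8 in JG and 28.8 ± 8.69 in MSC and was not called (1.42 ± 0.64, adjusted p = 0.187). Of the others, 1 at 136.64, 257.45 and 118.39 in the JG samples and at most 2.62 in the MSC samples had a log2 difference of 3.32 (adjusted p = 0.00218 over all probe sets), another had 2.05 (adjusted p = 0.0203), and the remaining 1 was not called (1.04, adjusted p = 0.143).

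**Figure D2:**
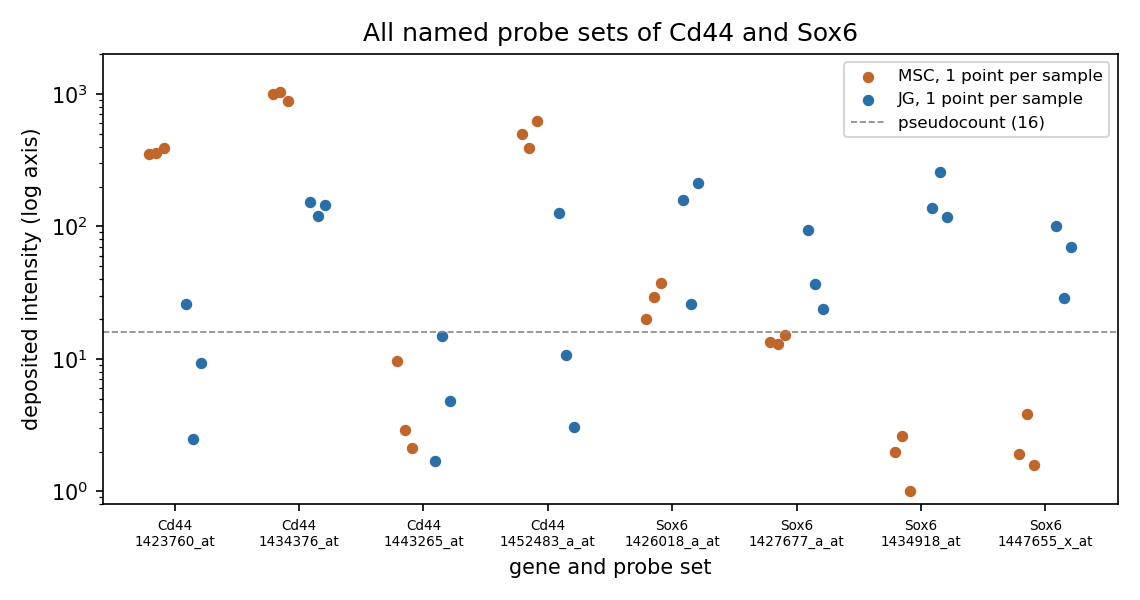
Deposited intensity (log axis) of the 4 probe sets of Cd44 and the 4 of Sox6 in each of the 6 samples, 1 point per sample, with the groups in different colours. JG points of Sox6 reach 257.45, and the dashed line is the pseudocount of 16.

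Markers of each of 4 nephron segments were higher in the JG samples. Of 20 measured proximal tubule markers 19 were called higher in JG, among them Kap, Slc34a1, Slc27a2 and Slc13a3, and the list median was 5.77. The thick ascending limb list had 9 of 13 members higher, led by Umod, Slc12a1, Egf and Kcnj1, and 1 lower (Ptgs2, -3.18, an inducible prostaglandin synthase). The distal tubule list had 8 of 10 higher, with Klk1 (6.17), the calcium-binding protein gene S100g (5.57) and the thiazide-sensitive cotransporter gene Slc12a3 (5.31), and the collecting duct list had 12 of 16 higher, with the proton pump subunit gene Atp6v1b1 (5.65) and the water channel gene Aqp3 (5.45). Slc12a3 was 859.6 ± 697 in JG and 1.31 ± 0.429 in MSC, and Aqp3 was 2015 ± 561 and 32.6 ± 19.2. With p-values adjusted over the list alone, 20, 10, 10 and 14 members were higher. In a competitive set test (camera) the lists stood above the other genes with adjusted p-values of 7.01e-22, 7.13e-08, 7.01e-07 and 6.39e-10, in the order given, and with adjusted p = 0.160, 0.164, 0.298 and 0.160 with an estimated correlation. The collecting duct count was 8 without any 1 of the MSC samples and the call of Ptgs2 was lost without MSC sample 2 or JG sample 3. The other genes named here kept their call with any 1 sample left out.

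Some endothelial and leukocyte markers were also called higher in JG. Of 19 endothelial markers 6 were called higher: Tek (381 ± 203 against 3.93 ± 1.93), Esam, Cldn5, Cdh5, Emcn and Robo4 (camera adjusted p = 0.000288, adjusted p = 0.160 with an estimated correlation). Counted as adjusted over the list alone, 11 were. Of 11 proteins whose absence is used to define MSC, H2-Aa (4.48), Cd34 (4.21) and Ptprc (1.00) were higher (camera adjusted p = 0.00679, adjusted p = 0.270 with an estimated correlation), and 5 were when adjusted over the list alone. Of 22 macrophage markers Laptm5 (4.69), C1qb (4.53), Csf1r (2.88) and Ptprc were higher (camera adjusted p = 0.0404, adjusted p = 0.411 with an estimated correlation), 5 when adjusted over the list alone. C1qb was called by 2 of its 3 probe sets, and with probe sets of suffix s or x left out its difference was -0.14 (adjusted p = 0.778). The macrophage call was lost without MSC sample 1 (adjusted p = 0.0779), MSC sample 3 (0.113), JG sample 1 (0.104) or JG sample 2 (0.0818), and also with quantile normalization, array weights (0.143), a pseudocount of 64 (0.0541) or probe sets of suffix s or x left out (0.0791). With genes under the median left out the endothelial call was lost (0.294) and too few of the 11 proteins remained for a test. The endothelial count fell to 2, 1 and 1 without MSC samples 1, 2 and 3, was 3 without JG sample 3 and 11 without JG sample 1. The macrophage count was 1 without MSC sample 1 or 3, 2 without JG sample 2 and 6 without JG sample 1. Among the genes named here only Tek, H2-Aa, Cd34 and Laptm5 kept their call whichever sample was left out.

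The remaining lists of other cell types were not called by camera. The lymphocyte list had Cd8a higher in 15 (adjusted p = 0.122), the neutrophil list Camp in 10 (adjusted p = 0.358), and the red cell and platelet list Slc4a1, Car2 and Itga2b in 9 (adjusted p = 0.139). The mesangial list had Sfrp2 and Hopx higher and Ptn, Pdgfrb and Fhl2 lower in 13 (adjusted p = 0.999), with a median of 0.48, a mean of 0.19 and a test in the opposite direction. The podocyte and parietal list had Cdkn1c higher and Synpo, Cldn1, Nes, Wt1 and Foxc2 lower in 13 (adjusted p = 0.477), with a median of 0.74 and a mean of -0.52. The nerve and Schwann cell list had Ncam1 and Tubb3 lower in 10 (adjusted p = 0.936), with a median of 0.11 and a mean of -0.37. When adjusted over the list alone, the 6 lists had 0, 1, 3, 2, 3 and 0 members higher in JG and 0, 0, 0, 3, 6 and 2 higher in MSC, in the order given. The 18 calls in these 6 lists were 8, 8 and 10 without MSC samples 1, 2 and 3, and 11 without JG sample 3. Sfrp2, Fhl2, Slc4a1, Foxc2, Wt1, Nes and Ncam1 kept their call with any 1 sample left out. Across all lists of other cell types, some members with the highest JG mean were not called (limma adjusted p from 0.0698 to 0.415). They were Agtr1a, H2-Ab1, Kit, Wnk1, Podxl, Plce1, Ehd3, Plat, Tyrobp, Cd2, Cd79b, Cd3d, S100a9, S100a8, Ltf, Hba-a2, Sox10 and Dbh.

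Genes tied to the renin cell itself went both ways. In the JG samples the proximal tubule list stood 5.77 above MSC, and which cells gave the transcripts below was not tested. Of 21 renin cell markers, the regulators of G protein signalling Rgs2 (388 ± 187 in JG, 8.23 ± 3.49 in MSC) and Rgs5 (1856 ± 659.8 and 148 ± 140.4), the angiotensin-converting enzyme gene Ace and the matricellular gene Sparcl1 were higher in JG, and Fibin, the connexin 45 gene Gjc1 and the prostaglandin receptor gene Ptger4 were lower. The list was not called (adjusted p = 0.442). Its 3 members lower in JG became 0 without any 1 of the MSC samples. The 4 higher in JG became 1, 2 and 2 without MSC samples 1, 2 and 3. Of 26 transcription factors linked to renin transcription Vdr (3.36), Nr1h3 (2.22) and Klf2 (1.22) were higher and Foxd1 (-3.44), Ets1 (-1.73) and Tbx18 (-1.22) lower (adjusted p = 0.999), with a median of -0.02 and a mean of 0.05. Of 25 genes of cyclic AMP signalling Rapgef3 and Adcy9 were higher and Pde4b, Akap12 and Prkar2b lower (adjusted p = 0.866). Of 18 genes of the renin-angiotensin and kinin systems Klk1, Ace, Kng1, Anpep and Mme were higher and none lower (adjusted p = 0.0988), of which Klk1 is also in the distal tubule list, and this list was called with genes under the 25th percentile left out (0.0330), without JG sample 3 (0.0413) or with a pseudocount of 1 (0.0371). Of 22 lysosomal genes Ctsh and Glb1 were higher and Gla lower (adjusted p = 0.119), and of 17 pericyte genes Rgs5 and Anpep were higher and Pdgfrb lower (adjusted p = 0.176). Adjusted over the list alone, the counts higher in JG were 4, 4, 3, 5, 2 and 2 and those higher in MSC 4, 3, 3, 1, 3 and 1. Together with the basement membrane list these 7 lists held 38 calls, which became 10, 14 and 17 without MSC samples 1, 2 and 3, 58 without JG sample 1 and 22 without JG sample 3. Rgs2, Vdr, Nr1h3, Foxd1, Pde4b, Klk1 and Kng1 kept their call with any 1 sample left out, and Rgs5 lost it without MSC sample 1 (adjusted p = 0.0603).

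**Figure D3:**
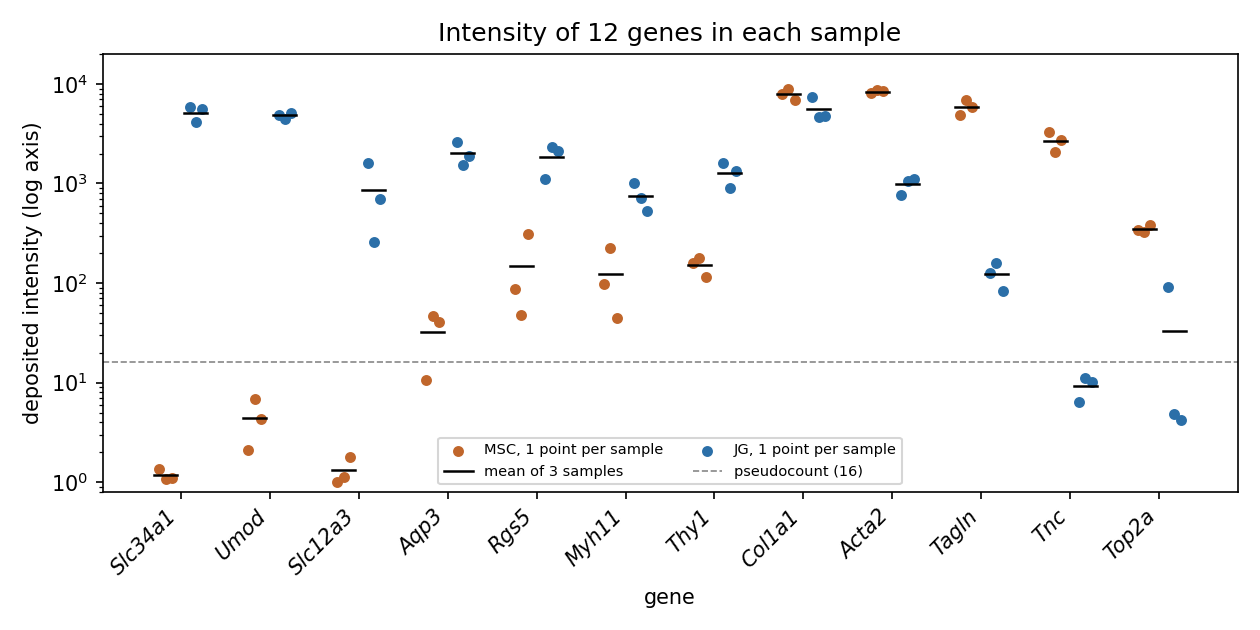
Deposited intensity (log axis) of 12 genes in each of the 3 MSC and 3 JG samples, with the group mean as a bar. Slc34a1 and Umod lie above the dashed pseudocount line only in the JG samples (means 5156 and 4823), and Tnc only in the MSC samples (mean 2687), while Acta2 is bright in both (8399 and 985).

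Most called contractile, actin and mechanically regulated genes were higher in MSC. Of 20 smooth muscle contractile genes 9 were higher in MSC, including Tagln (5879 ± 953 in MSC, 123 ± 38.0 in JG), Actg2, Lmod1 and Myl9, while the smooth muscle myosin heavy chain gene Myh11 (2.64, adjusted p = 0.0238) and Pln (1.77) were higher in JG. Acta2 was 8399 ± 321 in MSC and 985 ± 191 in JG. Of 21 actin and focal adhesion genes 11 were higher in MSC and none in JG, among them Actn1 (-3.42), Tpm4 (-3.39) and Vcl (-3.00). Of 24 target genes of the coactivators YAP and TAZ 11 were higher in MSC, led by Ankrd1 (-5.33), and Nt5e was higher in JG (3.24). Of 19 genes of the transforming growth factor beta response 8 were higher in MSC, including Ltbp2 (-4.91) and Tgfb3 (-4.52). Camera gave adjusted p-values of 0.00679, 3.04e-08, 7.82e-06 and 0.000373 for these 4 lists, and adjusted p = 0.298, 0.160, 0.196 and 0.164 with an estimated correlation. With p-values adjusted over the list alone, 9, 15, 14 and 9 members were higher in MSC. The counts without MSC samples 1, 2 and 3 were 5, 5 and 6 for the contractile list, 6 in each case for the actin list, 5, 4 and 6 for YAP and TAZ, and 5, 4 and 4 for the growth factor response. Without JG sample 3 the actin count was 6 and the growth factor response count 4. Myh11 and Pln, the 2 contractile genes higher in JG, became 0, 1 and 0 without MSC samples 1, 2 and 3 and 1 without JG sample 2 or 3. Among the 6 fits with 1 sample left out Nt5e was called only without JG sample 1, and its adjusted p reached 0.128 in the others. Tagln, Actg2, Lmod1, Myl9, Acta2, Actn1, Tpm4, Vcl, Ankrd1, Ltbp2 and Tgfb3 kept their call in every such fit.

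More collagen and protease genes were called higher in MSC than in JG, and some fibroblast genes were far higher in JG. Of 21 collagens and related proteins 8 were higher in MSC, with Tnc, Lox, Col11a1 and Thbs1 in the lead, while Col6a2 (4.96) and the elastin gene Eln (3.21) were higher in JG (camera adjusted p = 0.000519, adjusted p = 0.298 with an estimated correlation). Of 18 matrix proteases and inhibitors Timp1 (-5.11), Mmp11 (-3.60), Mmp10 and Mmp13 were higher in MSC and the urokinase gene Plau (2.67) in JG (camera adjusted p = 0.00179, adjusted p = 0.279 with an estimated correlation). Of 18 basement membrane genes Lama4, Col4a3, Col4a4, Sparcl1 and Npnt were higher in JG and Col4a1, Col4a2, Col4a5 and Lama5 in MSC (adjusted p = 0.646). The fibroblast list had Dpt (3205 ± 1666 in JG, 12.2 ± 9.83 in MSC), Pi16 (2200.2 ± 854 and 27.3 ± 17.0), Clec3b and Mfap5 higher in JG and Fbln2, Twist2 and Vim higher in MSC, of 22 (adjusted p = 0.803), with a median of -0.37 and a mean of 0.20. Col1a1, the main type I collagen chain, was 7935 ± 959 in MSC and 5602 ± 1599 in JG and was not called (adjusted p = 0.247). Of 18 surface proteins used to define MSC, Thy1 (1272 ± 347 in JG, 151 ± 32.1 in MSC) and Nt5e were higher in JG, and Nes, Pdgfrb, Itgb1, Itga5 and the sort antigen gene Cd44 in MSC (adjusted p = 0.369). Counted as adjusted over the list alone, the 5 lists had 3, 1, 8, 4 and 3 members higher in JG and 11, 7, 4, 5 and 5 higher in MSC.

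These matrix and surface counts changed when single samples were left out, which also leaves fewer residual degrees of freedom. The protease call was lost with genes under the median left out (adjusted p = 0.0940). The 8 collagen genes became 5 without any 1 of the MSC samples or JG sample 3, and 13 without JG sample 1, and the 4 proteases and inhibitors became 10 without JG sample 1. The 2 collagen-list genes higher in JG became 1 without MSC sample 1 or 2 or JG sample 3, and the 2 surface genes higher in JG became 1 without any 1 sample other than JG sample 1. The 3 fibroblast genes higher in MSC became 1 without MSC sample 2 or 3 and 7 without JG sample 1, and the 5 surface genes higher in MSC became 2 without any 1 of the MSC samples and 3 without JG sample 3. The 5 basement membrane genes higher in JG became 2 without MSC sample 1 or JG sample 3 and 3 without MSC sample 2, and the 4 higher in MSC became 1, 2 and 1 without MSC samples 1, 2 and 3. Tnc, Lox, Col11a1, Thbs1, Timp1, Mmp11, Plau, Mmp13, Eln, Lama4, Lama5, Dpt, Pi16, Clec3b, Fbln2, Cd44, Thy1 and Nes kept their call in every such fit.

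Most mitosis genes and a few replication genes were called higher in MSC. Of 25 mitosis genes 16 were called higher in MSC and none in JG, with Top2a at 349 ± 27.9 in MSC and 33.2 ± 49.6 in JG (90.48 in JG sample 1, 4.87 and 4.24 in the others), Kif11 at 278 ± 45.8 and 28.4 ± 19.5, and Cdk1 and Cdca8 among the others. The list median was -2.23 (camera adjusted p = 1.15e-10, adjusted p = 0.164 with an estimated correlation), and 22 were higher when adjusted over the list alone. Of 26 genes of DNA replication Rrm1 (-3.23), E2f1 (-2.36) and Mcm2 (-1.51) were higher in MSC (camera adjusted p = 0.00237, adjusted p = 0.270 with an estimated correlation), 8 when adjusted over the list alone. The cell cycle inhibitor gene Cdkn1a was higher in MSC too (3388 ± 509 against 205 ± 93.7), as were Igfbp3 and Mdm2, while Cdkn1c and Glb1 were higher in JG, in a list of 15 inhibitors and senescence-linked genes that was not called (adjusted p = 0.176). When adjusted over the list alone, 7 of these were higher in MSC and 2 in JG. JG sample 1 held the highest JG value of 12 of the 25 mitosis genes, and the list median against the MSC mean was -2.01, -2.35 and -2.17 in JG samples 1 to 3. The mitosis count was 13, 10 and 9 without MSC samples 1, 2 and 3. The replication count was 1 without any 1 of the MSC samples or JG sample 3, and 11 without JG sample 1, and the replication call was lost with genes under the median left out (adjusted p = 0.0684). The inhibitor list's 5 calls were 2, 1 and 3 without MSC samples 1, 2 and 3, 2 without JG sample 3 and 8 without JG sample 1. Of the genes named in this paragraph Kif11, Rrm1 and Cdkn1a kept their call in every such fit.

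All called genes of fatty acid oxidation were higher in JG, in the samples in which the proximal tubule list stood 5.77 above MSC. Of 19 measured members 9 were higher in JG and none in MSC, with the regulators Ppara (582 ± 495 in JG, 14.2 ± 3.75 in MSC) and Ppargc1a (630.1 ± 269 and 31.6 ± 17.3) and the peroxisomal enzyme gene Ehhadh (338 ± 130.5 and 15.0 ± 9.23) in the lead (camera adjusted p = 4.52e-06, adjusted p = 0.335 with an estimated correlation). Of 24 respiratory chain genes 6 were higher in JG, including Ndufv1 (1.73) and Cox5a, with camera adjusted p = 0.00100 and adjusted p = 0.577 with an estimated correlation. Of 18 cholesterol synthesis genes Fdps (-3.73), Msmo1, Lss and Fdft1 were higher in MSC (camera adjusted p = 0.0223, adjusted p = 0.298 with an estimated correlation), and of 20 endoplasmic reticulum folding genes Trib3, Ddit3 and Manf were (camera adjusted p = 0.0404, adjusted p = 0.335 with an estimated correlation). Adjusted over the list alone, 11, 8, 6 and 3 members of these 4 lists were called in the stated direction, and 1 cholesterol gene in the other. The fatty acid count was 5 and 4 without MSC samples 1 and 2, and the respiratory chain count 0, 1 and 1 without MSC samples 1, 2 and 3 and 3 without JG sample 3. The cholesterol count was 2 without any 1 of the MSC samples and 8 without JG sample 1, and the folding count 2, 1 and 1 without MSC samples 1, 2 and 3, 1 without JG sample 2, 2 without JG sample 3 and 7 without JG sample 1. The respiratory chain call was lost without JG sample 1 (adjusted p = 0.0708), the cholesterol call without JG sample 3 (0.0693), and the folding call without MSC sample 1 (0.0774), MSC sample 2 (0.0561), JG sample 2 (0.0811) or JG sample 3 (0.0904). Quantile normalization ended the cholesterol (0.0831) and folding (0.154) calls, as did leaving out genes under the 25th percentile (0.0752 and 0.139) or the median (0.213 and 0.294), and a pseudocount of 1 ended the folding call (0.0627). Ppara, Ppargc1a, Ehhadh, Fdps, Fdft1 and Trib3 kept their call in every such fit.

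Other metabolic lists went both ways and were not called. In glycolysis Ldhb was higher in JG (7459.7 ± 1006 against 1587 ± 358) and Hk2 (80.4 ± 50.3 against 1982 ± 714) and Eno2 were lower, of 18 (adjusted p = 0.936), with a median of 0.06 and a mean of -0.19. In the hypoxia list Epas1, Ndrg1, Car9 and Bnip3 were higher in JG and Hif1a, Ero1a, P4ha1 and P4ha2 higher in MSC, of 17 (adjusted p = 0.959), with a median of -0.37 and a mean of 0.16. Among 16 glutathione and NRF2 target genes Gsr and Me1 were higher in JG and Hmox1 and Srxn1 in MSC (adjusted p = 0.936), with a median of 0.11 and a mean of -0.03. With p-values adjusted over the list alone, 1, 5 and 4 were higher in JG and 2, 4 and 3 in MSC. The 15 calls of these 3 lists were 6, 6 and 8 without MSC samples 1, 2 and 3, and Ldhb, Hk2, Eno2, Ndrg1 and P4ha1 kept theirs in every such fit.

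More developmental regulators of the kidney were called higher in MSC than in JG. Of 20 measured, Wt1 (355 ± 82.6 in MSC, 9.30 ± 6.85 in JG), Foxd1 (-3.44), Meis2, Hoxc10, Hoxa11, Gdnf and Tbx18 were higher in MSC and Lhx1 in JG (camera adjusted p = 0.0231, adjusted p = 0.411 with an estimated correlation), with 10 and 1 when adjusted over the list alone. The count of 7 was 4 without MSC sample 2 or 3, and the call was lost without JG sample 2 (adjusted p = 0.0590), with the mean of a gene's probe sets (0.0817), with probe sets of suffix s or x left out (0.0791) or with genes under the median left out (0.0838). Lineage lists were not called by camera. The adipogenic list had Lpl, Cd36, Fabp4 and Cebpd higher in JG, of 12 (adjusted p = 0.122). The osteogenic list had Alpl and Msx1 higher in JG and Msx2, Tnfrsf11b and Bmp4 higher in MSC, of 11 (adjusted p = 0.995), with a median of 0.08, a mean of 0.11 and a test in the opposite direction. The chondrogenic list had none of 13 called by limma, with 2 at an unadjusted p under 0.05 (adjusted p = 0.995), and the stem cell factor list had Prom1 (7.08) higher in JG and Hmga2 (-4.47) higher in MSC, of 13 (adjusted p = 0.866). Counted as adjusted over the list alone, these 4 counts stayed at 4, 2, 0 and 1 for JG and 0, 3, 0 and 1 for MSC. Wt1, Foxd1, Meis2, Hoxc10, Lhx1, Lpl, Cd36, Fabp4, Alpl, Msx2, Tnfrsf11b, Prom1 and Hmga2 kept their call with any 1 sample left out.

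In the signalling lists other than that of bone morphogenetic protein and hedgehog genes, called members went both ways. Of 24 growth factors and receptors Igfbp5 (5967 ± 299.6 in JG, 30.3 ± 27.1 in MSC), Igfbp4 and Fgf10 were higher in JG, and Igfbp2, Igfbp3, Pdgfrb, Vegfc, Hbegf, Nrg1 and Fgfr2 in MSC (adjusted p = 0.0993). With probe sets of suffix s or x left out Vegfc turned to 0.44 (adjusted p = 0.382). Of 23 Wnt pathway genes Sfrp2 (6.71) was higher in JG and Dkk3 (-6.74), Fzd2 and Wnt9a in MSC (adjusted p = 0.265). Of 17 bone morphogenetic protein and hedgehog genes Grem1, Gli3 and Bmp4 were higher in MSC (adjusted p = 0.265), and of 17 Notch genes Nrarp and Notch1 were higher in JG and Maml2 in MSC (adjusted p = 0.798). Of 20 potassium and calcium channel genes Cacna1d (5.75), Kcnj15 (5.72), Kcnj16 and Trpc1 were higher in JG and Kcnma1 (-4.81) and Cacna2d1 in MSC (adjusted p = 0.265). Of 15 circadian genes Hlf (5.83) and Tef were higher in JG and Clock in MSC (adjusted p = 0.477). When adjusted over the list alone, the counts higher in JG were 3, 2, 0, 3, 4 and 5 and those higher in MSC 8, 5, 3, 1, 3 and 3. The growth factor list was called without MSC sample 3 (adjusted p = 0.0343). The 29 calls in these 6 lists were 18 without MSC sample 1 or 2 and 45 without JG sample 1. Igfbp5, Igfbp4, Igfbp2, Vegfc, Hbegf, Sfrp2, Dkk3, Grem1, Gli3, Nrarp, Notch1, Cacna1d, Kcnj15, Kcnj16, Trpc1, Kcnma1 and Hlf kept their call in every such fit.

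Lists of dissociation stress and immune signalling were not called. Of 22 immediate-early genes Fosb (1321 ± 962 in JG, 22.9 ± 7.64 in MSC), Atf3 and Klf2 were higher in JG and Ier3 in MSC (adjusted p = 0.866). Of 13 heat shock genes Hspa1a was higher in JG and Hspb1 and Dnajb4 in MSC (adjusted p = 0.205). Of 22 chemokines and cytokines Ccl11 (859 ± 173 in JG, 1.59 ± 0.617 in MSC) and Cxcl16 were higher in JG and Cxcl12 (172 ± 112 in JG, 4816 ± 714 in MSC), Ccl2 and Ccl7 in MSC (adjusted p = 0.999), with a median of 0.10 and a mean of -0.16. Of 12 complement genes C1qb, Cd55 and Cfb were higher in JG (adjusted p = 0.265), where C1qb carries the disagreement between probe sets given above. Of 19 interferon-induced genes Oas2 was higher in JG (adjusted p = 0.986), with a median of -0.07, a mean of -0.01 and a test in the opposite direction, and of 11 class I presentation genes none was called by limma, with 2 at an unadjusted p under 0.05 (adjusted p = 0.913). Adjusted over the list alone, the counts higher in JG were 4, 1, 4, 4, 0 and 0 and those higher in MSC 2, 2, 3, 1, 0 and 0. The 7 stress calls were 1, 1 and 0 without MSC samples 1, 2 and 3, 4 without JG sample 3 and 13 without JG sample 1, and the 9 immune calls were 5 without any 1 of the MSC samples and 19 without JG sample 1. Ccl11, Cxcl12, Ccl7 and Cd55 kept their call in every such fit.

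All 20 list calls were made at a preset correlation of 0.01 between the genes of a list. None of the 55 lists was called with an estimated correlation (9 and 11 lists, higher in JG and in MSC, against 0 and 0). A higher correlation does not account for every loss. The endothelial list had an estimated correlation of -0.00332, below the preset, and its camera adjusted p still rose from 0.000288 to 0.160. At a preset correlation camera takes its degrees of freedom from the number of genes. With an estimated correlation it takes the few residual degrees of freedom of 3 samples against 3. The lack of calls with an estimated correlation therefore cannot by itself be read as correlation between genes. At an unadjusted p under 0.05 camera with an estimated correlation had 10 lists, and fry, which tests a list by itself, called 32, without that of the respiratory chain (adjusted p = 0.0625). With the main processing of all 6 samples, fry but not camera called the lists of renin cell markers, renin-angiotensin and kinin systems, cell cycle inhibitors, adipogenic and circadian genes. The same held for Notch, bone morphogenetic protein and hedgehog, growth factor and channel genes. Among other cell types it held for lymphocytes, neutrophils, red cells and platelets, and podocyte and parietal cells. A single gene in 3 samples against 3 has a smallest exact permutation p of 0.1, and the number of arrays limits the precision of every value.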

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

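Leaving out probe sets with the suffix s or x was the 1 alternative chosen after seeing the data. The cause of the changes below was not tested, except that leaving out a sample or adding a block leaves fewer residual degrees of freedom. Camera with an estimated correlation also has far fewer degrees of freedom than camera at the preset. Of 260 named genes 121 had the same call under all 18 alternatives, 124 lost it and 14 gained it under some, and C1qb reversed to -0.14 (adjusted p = 0.778) and Vegfc to 0.44 (0.382) with that suffix left out. The 2790 called genes (1401 higher in JG, 1389 in MSC) became 6177 (3208, 2969) with array weights and 1314 (811, 503) with an unmoderated t statistic. At 2-fold the 2742 became 5350 (2676, 2674) and 1192 (728, 464), and the 287 called genes of the lists became 467 and 159. With single samples left out, called genes ran from 1139 to 5194 (719 to 2551 higher in JG, 411 to 2643 in MSC), at 2-fold from 1139 to 4905 (719 to 2357, 411 to 2548), and list genes from 160 to 400. With the replicate number as a block 1613 genes were called (903, 710), all at least 2-fold. Same-numbered samples deviated with r = -0.20, -0.01 and -0.01, and no sample correlated best with its own number. These values gave no sign of pairing by number, but 3 samples per group cannot exclude it. The 20 called lists (9 higher in JG, 11 in MSC) became 13 (6 in MSC) with genes under the median left out, where 48 lists were tested, 0 (0 and 0) with an estimated correlation and 32 (17 in JG) by fry, which asks another question. The correlations of 0.759 between groups, 0.973 within MSC and 0.860 within JG became 0.448, 0.946 and 0.748 over genes above the median, and within MSC 0.971 with the mean of a gene's probe sets and 0.961 with a pseudocount of 1. The median difference of all genes was 0.07, 0.10 with a pseudocount of 1, and -0.07 and -0.30 with genes under the 25th percentile and under the median left out. Cd44 kept its direction and call in all alternatives. Signal near the floor limits dim genes, whose differences shrink with the pseudocount.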

Other observations

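The tests of the tubule and mitosis patterns, of the gene families and of the splits were chosen after their results or related results were seen, and those of the spread and of the added fibroblast list before. Several gene families with epithelial members had more genes called higher in JG than in MSC. Of 343 solute carrier genes 85 were higher in JG and 14 in MSC (camera adjusted p = 3.30e-06 over 8 families, adjusted p = 0.0663 with an estimated correlation), with Slc34a1 and Slc27a2 at one end and the amino acid transporter gene Slc7a5 (-3.78) at the other. Of 72 cytochrome P450 genes 14 were higher in JG, such as Cyp4b1 (6.98) and Cyp2j5 (6.74), and only Cyp1b1 (-4.96) was higher in MSC (adjusted p = 9.13e-05, adjusted p = 0.0451 with an estimated correlation). Of 11 UDP-glucuronosyltransferase genes 6 were higher in JG (adjusted p = 4.07e-05, adjusted p = 0.0774 with an estimated correlation). Among 24 claudins, which seal epithelial junctions, Cldn8, Cldn2, Cldn10, Cldn16 and Cldn5 were higher in JG and Cldn11 and Cldn1 in MSC (adjusted p = 0.0404, adjusted p = 0.296 with an estimated correlation). Of 20 proton pump genes Atp6v1b1, Atp6v0d2 and Atp6v0a4 were higher in JG (adjusted p = 0.124), and Hox genes (2 higher in JG and 4 in MSC of 34, adjusted p = 0.286), S100 genes (S100a1 of 12, adjusted p = 0.953) and kinesins (2 and 5 of 37, adjusted p = 0.284) were not called. Under quantile normalization, median centring and pseudocounts of 1 and 64, the sign of a family's median changed only for the S100 genes (0.05 and 0.04 with quantile normalization and a pseudocount of 64). A pseudocount of 64 gave 75 solute carrier, 10 cytochrome P450 and 3 claudin genes higher in JG, and 15, 1 and 1 higher in MSC. With 1 sample left out Cldn5, Cldn16, Cldn1 and S100a1 lost their call in some fits. The haemoglobin gene Hbb-b2 was 3601 ± 2251 in JG and 2.01 ± 1.75 in MSC (adjusted p = 0.000942), while Hba-a2 was 1089 ± 798 in JG and 2721 ± 609 in MSC (adjusted p = 0.107).

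The fibroblast genes that were far higher in JG, Dpt and Pi16, are known from fibroblasts of the vessel adventitia, so a list of 22 further adventitial genes was written before its result was seen. Its median difference was 1.29, with 8 members higher in JG and Smoc2 higher in MSC (camera p = 0.000367, p = 0.196 with an estimated correlation). Scara5 (5.55), Efhd1 (6.36), Dpp4 (4.67) and Sema3c (3.80) were among the 8, and Dpp4 is also a brush border protein of the proximal tubule. Smoc2 lost its call in 5 of the 6 fits with 1 sample left out (adjusted p up to 0.0891) and Sema3c without MSC sample 2 (0.0503). Adventitial fibroblasts next to the sorted arteriolar cells are a candidate source of these transcripts. A sort for the reporter is meant to exclude them, but its purity was not given in the sources used here and their share was not measured.

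In each of the 4 segment lists most of the tubule markers were higher in JG and a bright marker stood out in every JG sample, with Kap at 6959 ± 1485, and 0 proximal tubule markers are also in another list. Another probe set was available for 30 of the 59 measured tubule genes. These 53 other probe sets had a median difference of 2.00, with 46 above 0 and 24 called higher in JG. A few cross-reacting probe sets therefore do not account for the pattern in those 30 genes. The scale of the arrays does not account for the pattern either, because the median of the 59 tubule genes was 4.61 as deposited and 4.72 after quantile normalization. Tubule cells or their RNA in the JG samples, in all 4 segments, could give such values. The reporter sort is meant to exclude such cells, but its purity was not given in the sources used here. Expression of these genes by JG cells themselves was not tested and stays open.

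Mitosis genes had a list median of -2.23. If RNA of other cells only diluted the stromal RNA of the JG samples, fibroblast genes would lie as low. Their median was higher by 1.85 (95% bootstrap interval over genes 0.78 to 3.38), which taken alone goes against dilution. The interval treats the genes as independent and leaves out the spread between samples. The members of the fibroblast list also went both ways with a standard deviation of 2.70, and other fibroblasts may add to some of them. The gap depends on the list taken for stromal RNA. The list of matrix proteases and inhibitors had a median of -1.65 and the collagen list -1.11, while the pericyte list had 0.49. Dilution therefore cannot be told apart from a change in the cells. Growth of the MSC in culture may account for the mitosis genes, and this cannot be told apart from the cell type with these samples, since a median of -2.23 is what either would give.

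The JG samples differed more among themselves than the MSC samples did, with a ratio of median standard deviations of 2.09. The ratio was 2.12 after quantile normalization and 2.14 among genes above the 75th percentile, which argues against array scale and against dim genes as the cause. A varying share of tubule cells would move tubule and stromal genes in opposite directions in each JG sample, and this was seen in 1 of the 3 samples. Median deviations in JG samples 1 to 3 were 0.32, -0.38 and 0.11 for tubule genes and 0.71, -0.52 and -0.10 for stromal genes. These values had no further normalization, and JG sample 2 had the lowest trimmed mean (153). Array scale can move both sets together, so the test cannot decide and leaves a varying share open. Animals, sorts and RNA yield were not given in the sources used here, and apart from the share of tubule cells no biological explanation was tested.

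The real split of the 6 samples gave 2790 called genes and the highest of the other 9 splits gave 0. The real split was thus 1 of 10, and 10 splits are too few for a share under 0.05.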
